A study of Mus musculus with 10 samples.

How the data were processed

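RNA sequencing was carried out on 10 samples of mouse inguinal white adipose tissue, 5 labelled Flox and 5 labelled GHR Knockdown, all at 20 months of age. The second group is called Ad-GHRKO here, after the series. Per the labels' protocols, polyadenylated RNA was selected with oligo(dT) beads, fragmented and copied with random primers, and the second strand was marked during synthesis. The aligner, the counting tool and whether counting used strand are not given in the sources used here. The authors deposited a table of FPKM values (fragments per kilobase of gene, scaled to each library's total of assigned fragments), 1 column per library, per the file headers, with functional annotation for each gene. The submitters' processing notes name the build GRCm39. Of 31253 gene identifiers also found in GENCODE release M21, 31124 (99.59%) had exactly the GRCm38 coordinates of that release, so coordinates are given as GRCm38 as they stand in the table. Column names matched the sample titles, and every value column was mapped to a sample.

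FPKM values were multiplied by the exon length of each gene in GENCODE M21 and by a constant for each library. This gave whole reads, within a tolerance of 0.01, for 99.24% to 99.32% of values in each library and for 31053 genes in every library. The recovered depth was 14.6 to 19.3 M reads (M, mega). At the mean of 17.9 M reads, 1 FPKM on a transcript of 1 kilobase is about 18 reads, which sets the precision at low levels. FPKM is relative to each library's total, so very abundant transcripts move all others. Cfd, which took 1.48% ± 0.483 of Flox reads and 0.185% ± 0.0505 of Ad-GHRKO reads (SD, n = 5 each), does so slightly. The 26 genes of the skeletal muscle list took 18.4% of the reads of Ad-GHRKO 1, 10.4% of Flox 5 and 7.29% of Flox 3. These transcripts lower the other values of these libraries by more. Reads on muscle genes outside the list are not counted in these shares.

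Genes with at least 1 FPKM in at least 5 libraries were tested, 12785 in all. Tests used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend, two-sided, and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Ghr and the list scores were also compared by exact two-sided permutation tests over 252 assignments. Before the data were examined, 36 gene lists were fixed, and the 33 with at least 5 tested members (the sex chromosome list aside) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. A list score is the mean log2(FPKM + 1) over its tested members. The annotation for the pathway test was gene ontology biological process, in sets of 10 to 300 genes, because the KEGG column holds orthology identifiers and not pathways.

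The named genes follow a rule fixed at the same time. It takes Ghr, then the 12 largest positive and 12 largest negative log2 changes among genes past 0.05 with a mean of at least 2 FPKM and all libraries apart, leaving out predicted, Rik and receptor or immunoglobulin segment genes. From each pathway list it takes up to 4 members past the threshold with the smallest p, or with none, up to 2 with the smallest p. From each cell type or handling list it takes up to 2 most abundant members and up to 2 past the threshold, and the script applied this to the sex chromosome list too, which gave Ddx3y. Not all genes that the rule gives are named, and 1 of them is not reported here. Adipoq, Lep, Retn, Fasn, Thrsp, Elovl6, Lgals3, Gpnmb, Cd9, Spp1, Ctsk, Xist and Gm23935 were chosen after their values were seen.

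The alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, no filter, a filter of 5 FPKM, median ratio scaling, quantile normalization, TPM rescaling, a replicate block, array weights, a robust prior, covariates for B cell, skeletal muscle and epithelial scores, leaving out each library, for gene sets the estimated correlation, fry and sets of 5 to 500 genes, and for list scores the median of the members. Added after seeing the data were fits without the 3 muscle-rich libraries, without the 4 libraries with muscle reads, with limma voom on the recovered reads, and with the trend of each library with exon length or with GC content removed (lowess, span 0.3). No 2 libraries held identical values.

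The tests were tried on simulated data for the comparison of Ad-GHRKO with Flox, with counts drawn for 31050 genes from the Flox means and real depths. Of 200 genes changed by design, 193 were among the 12960 tested. Recovery was 15.4% at 1.5-fold, 81.8% at 2-fold and 100% at 4-fold, and 12 of 138 calls (8.7%) were false. The simulated genes shared 1 dispersion and varied independently, and no simulated library differed in muscle reads. These rates are therefore not the power of the real comparison. Camera called 0 of 200 random lists of independent genes. Python 3.11.15 with pandas 2.3.3 was used to read the table and matplotlib 3.10.9 for the plots.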

Results

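Gene expression was measured by RNA sequencing in subcutaneous (inguinal) white adipose tissue of 20-month-old mice of 2 genotypes. The series names an adipose-specific knockout of the growth hormone receptor (Ad-GHRKO), the sample labels give the genotype of the same mice as GHR Knockdown, and Flox mice are the comparison genotype. There were 5 libraries per genotype, 1 for each deposited sample. The labels do not state that each sample came from a separate animal, so the p-values measure the spread between these samples. The deposited table lists 31285 genes in FPKM. Reads recovered from these values came to 17.8 ± 1.22 M per Flox library and 18.1 ± 1.96 M per Ad-GHRKO library (mean ± SD, n = 5 each; M, mega), with a range of 14.6 to 19.3 M. The first principal component held 42.0% of the variance and did not part the genotypes (exact permutation p = 0.341), and the second held 21.2% and did (exact permutation p = 0.00794). The comparison asks how the transcripts of this depot differ between the genotypes in old mice.

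Ghr, the growth hormone receptor gene (ENSMUSG00000055737, chromosome 15, 3317760 to 3583492, minus strand, GRCm38), was lower in every Ad-GHRKO library. Its level was 93.5 ± 21.9 FPKM in Flox and 16.6 ± 2.71 FPKM in Ad-GHRKO (SD, n = 5 each). The Flox libraries 1 to 5 held 72.9, 130, 89.7, 80.9 and 94.1 FPKM, and the Ad-GHRKO libraries 1 to 5 held 15.1, 20.1, 13.0, 16.7 and 17.9 FPKM. On the log2(FPKM + 1) scale Ghr fell by 2.41 (SE 0.17, limma adjusted p = 6.54e-05). An exact two-sided permutation test gave p = 0.00794, the smallest that 5 against 5 libraries allow. The value covers the whole gene, so it can include reads outside the deleted part. Igf1, which encodes a growth factor induced by growth hormone (ENSMUSG00000020053, chromosome 10, 87858265 to 87937042, plus strand), fell from 18.3 ± 5.91 to 5.51 ± 1.85 FPKM (log2 change -1.56, SE 0.22, adjusted p = 0.00468). Igf1 overlaps an antisense gene, Igf1os, and the use of strand in counting is not stated. Of the 23 measured genes in the list of growth hormone and IGF signalling, these 2 fell and 21 did not pass, while 5 were lower adjusted over the list alone. The list itself did not pass (camera adjusted p = 0.163, p = 0.396 with an estimated correlation), though it passed as lower without Flox 2 (camera adjusted p = 0.0344). Its median log2 change was 0.12 where its mean was -0.18. Both that mean and the call without Flox 2 include Ghr, the targeted gene.

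**Figure D1:**
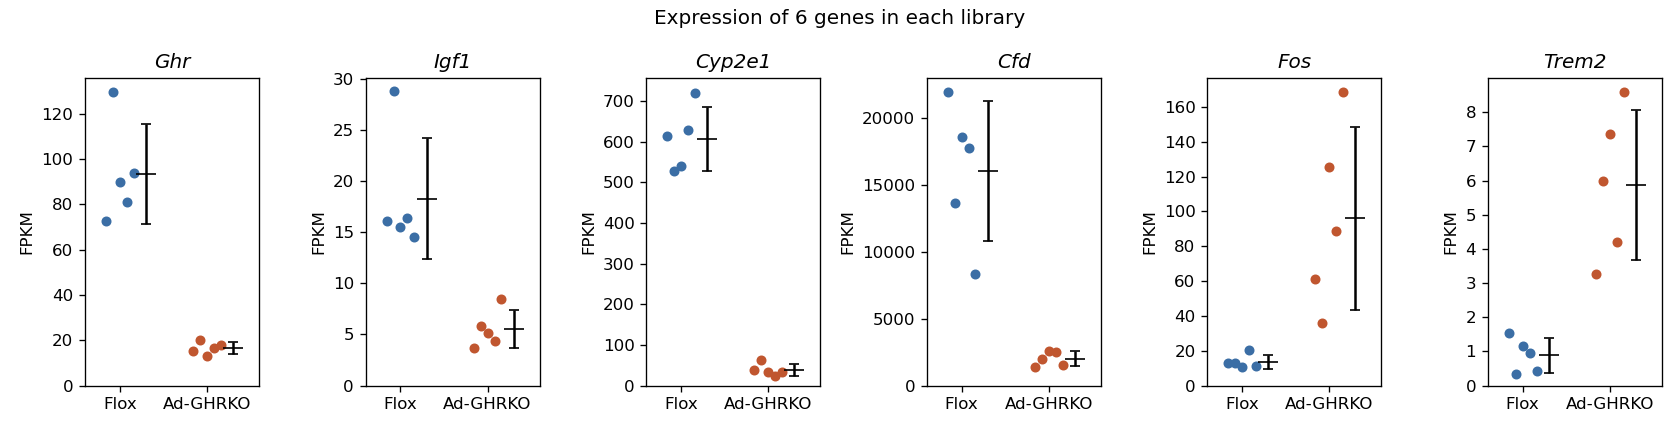
FPKM of Ghr, Igf1, Cyp2e1, Cfd, Fos and Trem2 on linear axes starting at 0, with 1 point per library (n = 5 per genotype) and the mean with its SD as a bar. Every Ad-GHRKO library lies below every Flox library for Ghr, Igf1, Cyp2e1 and Cfd, and above every Flox library for Fos and Trem2.

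Across the genome, transcripts of fat synthesis and adipocyte products were among those that fell, and matrix-associated and immediate early transcripts among those that rose. Cyp2e1, a cytochrome P450, fell from 606 ± 77.9 to 38.04 ± 14.5 FPKM (log2 change -4.02, SE 0.23, adjusted p = 1.94e-05). Cfd, the adipokine adipsin, fell from 16079 ± 5237 to 2006 ± 550 FPKM (log2 change -2.97, SE 0.34, adjusted p = 0.00169). Thbs1, a matrix glycoprotein, rose from 9.56 ± 10.6 to 145 ± 103 FPKM (log2 change 3.99, SE 0.69, adjusted p = 0.0142). Of 12785 genes tested, 280 changed at an adjusted p of 0.05, with 99 higher and 181 lower, and 66 of the higher and 99 of the lower changed by at least 2-fold. Among all genes tested, 635 (4.97%) had every library of one genotype above every library of the other, where chance gives 0.794%. An unadjusted p of 0.05 was passed by 2091 genes, where chance gives 639. Both chance values are averages, and genes that vary together can take a single grouping far from them. Neither count was taken over other splits of the libraries. With no filter on low values, the calls of Cfd (adjusted p = 0.144), Thbs1 (0.0561), Sfrp5 (0.0543), Junb (0.0514), Agpat2 (0.0572) and Gsta4 (0.0511) ended, though each held when any 1 library was left out.

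Angptl8, a secreted regulator of lipoprotein lipase, fell by 3.30 on the log2 scale (adjusted p = 0.00877), and Cyp2f2 fell by 3.25 (adjusted p = 0.00436). Tst, a mitochondrial sulfurtransferase, fell by 2.96 (adjusted p = 0.000112), and Sctr, the secretin receptor, by 2.49 (adjusted p = 0.00223). H2-Q10 and Rasd1 had log2 changes of -2.22 and -2.51 (adjusted p = 0.00266 and 0.0313). The matricellular genes Ccn1 and Ccn5 rose by 2.82 and 2.71 (adjusted p = 0.00964 and 0.0196), and the secreted Wnt antagonist Sfrp5 rose from 47.7 ± 32.5 to 263 ± 88.4 FPKM (adjusted p = 0.0142). Cdkl4 rose from 0.652 ± 0.704 to 10.5 ± 3.35 FPKM (adjusted p = 0.000666). Mmp12 and Atp6v0d2, both expressed by macrophages, had log2 changes of 2.76 and 2.69 (adjusted p = 0.00747 and 0.0465). Cyp2f2, Cyp2e1 and H2-Q10 belong to families of similar genes, so their values are uncertain. Angptl8 lies within Dock6, Cyp2f2 overlaps Gm15883, and without the 4 libraries with muscle reads the log2 change of Angptl8 was -2.81 and its call ended (0.0858, 6 libraries left). The call of Atp6v0d2 ended when any of 8 single libraries was left out (adjusted p up to 0.123), that of Rasd1 without any of 6 (up to 0.0682) and that of Ccn5 without Flox 2 or Ad-GHRKO 5 (up to 0.0560).

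The number of changed genes depended on single libraries. It was 1185 without Ad-GHRKO 1, of which 778 were higher. It was 135 without Flox 2, 153 without Flox 3, 137 without Flox 4, 167 without Flox 5, 116 without Ad-GHRKO 3, 154 without Ad-GHRKO 4 and 134 without Ad-GHRKO 5. The 26 genes of the skeletal muscle list took 18.4% of the reads of Ad-GHRKO 1, 10.4% of Flox 5, 7.29% of Flox 3 and 0.239% of Ad-GHRKO 5, and 0.007% to 0.018% in the other libraries. Muscle genes outside the list are not counted, so the whole share of muscle transcripts is larger. Without Flox 3, Flox 5 and Ad-GHRKO 1, a choice made after seeing the data, 777 genes changed (378 higher, 399 lower). Of the 280 genes, 219 were among them and all 280 kept their direction. For 255 of the 280, all libraries of one genotype already lay above all of the other, so leaving out libraries could not turn them. Rescaling each library to TPM moved the share of lower calls from 64.6% to 39.7% and the median log2 change of all genes from 0.04 to 0.15.

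**Figure D2:**
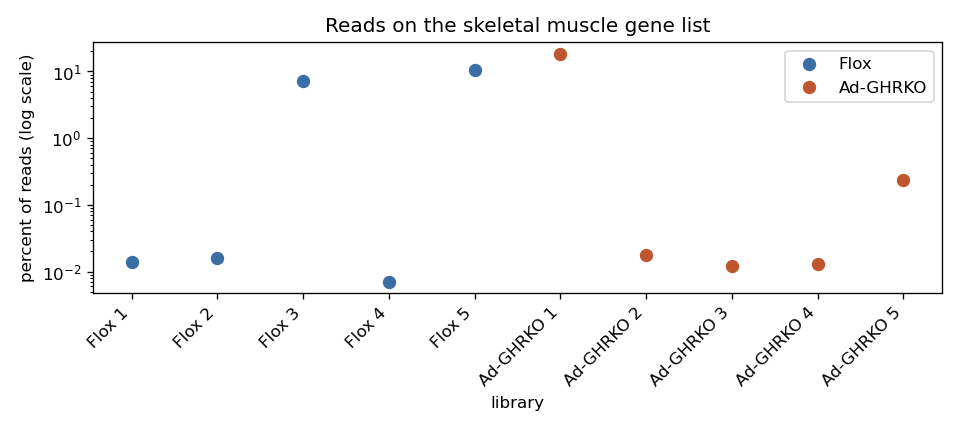
Percent of recovered reads on the skeletal muscle gene list in each library, on a log axis, with 1 point per library. Flox 3, Flox 5 and Ad-GHRKO 1 lie at 7.29%, 10.4% and 18.4%, Ad-GHRKO 5 at 0.239%, and the other libraries at 0.018% or less.

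Genes of de novo lipogenesis, the synthesis of fatty acids from acetyl-CoA, were lower as a list in Ad-GHRKO. Of 22 measured members, 9 fell, none rose and 13 did not pass, and 13 were lower adjusted over the list alone. Acaca, which encodes acetyl-CoA carboxylase, fell from 53.1 ± 23.7 to 7.66 ± 2.09 FPKM (log2 change -2.52, SE 0.35, adjusted p = 0.00422). Aacs, acetoacetyl-CoA synthetase, fell from 67.1 ± 18.3 to 19.2 ± 3.96 FPKM (adjusted p = 0.00169). Srebf1, a transcription factor of lipid synthesis, fell from 77.4 ± 13.0 to 29.1 ± 4.99 FPKM (adjusted p = 0.00207), and Insig1, a regulator of its processing, from 84.5 ± 29.4 to 21.3 ± 4.38 FPKM (adjusted p = 0.00237). Srebf1 overlaps Rai1, and without the 4 libraries with muscle reads the log2 change of Acaca was -1.91 and its call ended (0.0533, 6 libraries left). The list passed (camera adjusted p = 7.84e-12), with p = 0.0282 with an estimated correlation, where the call was lost (0.327 after adjustment). Of 33 lists tested, 15 passed camera with the preset correlation of 0.01, and 4 passed fry. With an estimated correlation 0 passed camera, and 4 had an unadjusted p under 0.05. Other splits of the 10 libraries into 5 and 5 gave at least as many lists in 47 of 100 cases, the real one included, so the number of lists does not set the genotypes apart.

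**Figure D3:**
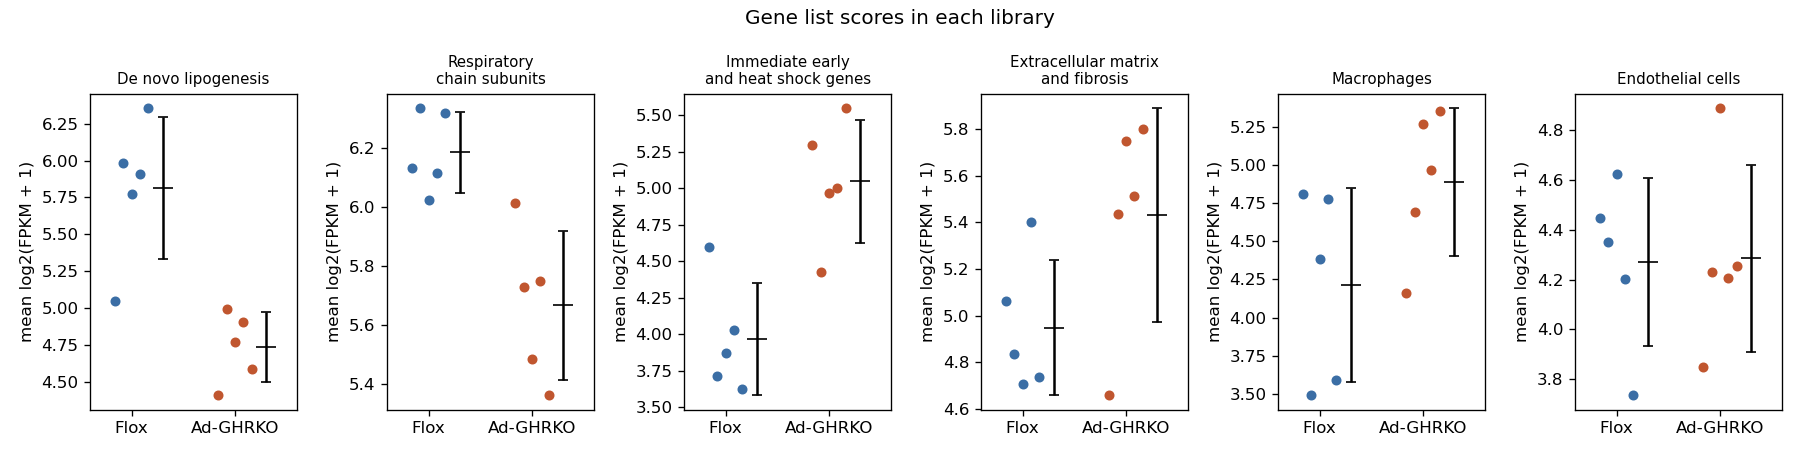
Mean log2(FPKM + 1) over the tested members of 6 gene lists, with 1 point per library (n = 5 per genotype) and the mean with its SD as a bar; the axes do not start at 0. Every Ad-GHRKO library lies below every Flox library for de novo lipogenesis and respiratory chain subunits, and the genotypes overlap for the other lists shown.

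Lipolysis genes were lower as a list, with 4 of 23 members down and 19 not past the test (1 higher and 7 lower adjusted over the list alone), and 8 of the 23 had positive log2 changes of any size. Adrb3, the beta-3 adrenergic receptor, fell from 184 ± 61.3 to 33.4 ± 8.93 FPKM (adjusted p = 0.00169), and Hcar1, the lactate receptor, from 46.2 ± 12.8 to 10.99 ± 3.72 FPKM (adjusted p = 0.00223). G0s2, an inhibitor of adipose triglyceride lipase, fell from 565 ± 119 to 182 ± 75.4 FPKM (adjusted p = 0.00811), and Cidea, a lipid droplet protein, from 38.8 ± 22.9 to 6.91 ± 3.40 FPKM (adjusted p = 0.0297). Hcar1 and G0s2 restrain lipolysis and Adrb3 stimulates it. The list had camera adjusted p = 0.000142, with p = 0.195 with an estimated correlation. Its call ended with array weights (adjusted p = 0.0646) and without the 4 libraries with muscle reads (0.127). In triglyceride synthesis and fatty acid uptake, 2 of 21 fell and 19 did not pass (6 lower adjusted over the list alone; camera adjusted p = 0.000453, p = 0.129 with an estimated correlation, and 0.0737 after adjustment without the 4 libraries with muscle reads). These were Agpat2, an acyltransferase, with a log2 change of -1.70 (adjusted p = 0.0163), and Mogat1, with -1.41 (adjusted p = 0.0407). Adrb3, Cidea, G0s2 and Agpat2 overlap other genes. The calls of Cidea and Mogat1 ended without any of 6 and of 7 single libraries (adjusted p up to 0.0816 and 0.108).

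Adipocyte identity genes were lower as a list, with 3 of 27 down and 24 not past the test (2 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.00037, p = 0.284 with an estimated correlation). The list's call ended with quantile normalization (adjusted p = 0.0560), with array weights (0.0799) and without the 4 libraries with muscle reads (0.127). Its score was 6.52 in the muscle-rich library Ad-GHRKO 1 and 7.20 to 7.75 in the other Ad-GHRKO libraries, against 7.43 to 8.11 in Flox, and without Ad-GHRKO 1 the list's mean relative to all genes was -0.33, against -0.46 with all. Cfd and Adrb3 were among the 3, while Fabp4, the fatty acid binding protein of adipocytes, was at 2134 ± 570 and 2101 ± 724 FPKM (adjusted p = 0.934). Of the thermogenic and beige adipocyte genes, Cidea fell and 15 of 16 did not pass (3 lower adjusted over the list alone; camera adjusted p = 0.0106). With an estimated correlation p = 0.0159, and the call was lost (0.327 after adjustment). It also ended without Flox 5 (adjusted p = 0.0797), without the 3 muscle-rich libraries (0.122), with either other filter on low values (0.0564 and 0.158) and with the GC trend removed (0.0629). Brown adipocyte markers did not pass (1 of 5 lower, 2 adjusted over the list alone; camera adjusted p = 0.154, p = 0.28 with an estimated correlation), and passed as lower without Flox 4 (0.0457) or Ad-GHRKO 1 (0.0197). Cox8b was at 100 ± 42.6 and 46.5 ± 73.7 FPKM (adjusted p = 0.176), with 178 FPKM in the muscle-rich library Ad-GHRKO 1, without which the adjusted p was 0.00306.

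Genes of the mitochondrial respiratory chain were lower as a list. Of 74 measured subunits, 7 fell, none rose and 67 did not pass, and 47 were lower adjusted over the list alone. Cox5b, a subunit of cytochrome c oxidase, fell from 124 ± 9.19 to 72.1 ± 11.7 FPKM (log2 change -0.79, SE 0.14, adjusted p = 0.0196). Uqcrh and Uqcrq of complex III and Atp5k of ATP synthase had log2 changes of -0.76, -0.91 and -0.84 (adjusted p = 0.0246, 0.0446 and 0.0385). The list had camera adjusted p = 3.78e-30, and p = 0.0396 with an estimated correlation, where the call was lost (0.327 after adjustment). Its mean score was 6.18 ± 0.136 in Flox and 5.67 ± 0.252 in Ad-GHRKO, with an exact permutation p = 0.00794 (0.131 after adjustment over the lists). The calls of Cox5b, Uqcrh, Uqcrq and Atp5k ended without any of 3, 7, 9 and 8 single libraries (adjusted p up to 0.0699, 0.0797, 0.123 and 0.115), and all 4 ended with median ratio scaling. Those of Cox5b, Uqcrq and Atp5k also ended with TPM rescaling and with the exon length trend removed, and those of Uqcrq and Atp5k with the GC trend removed.

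TCA cycle genes were lower as a list (camera adjusted p = 4.87e-07, p = 0.117 with an estimated correlation). Pcx, pyruvate carboxylase, was the 1 of 26 that fell (log2 change -1.34, adjusted p = 0.0436), and 1 was higher and 10 lower adjusted over the list alone. Its call ended without any of 7 single libraries (adjusted p up to 0.115). Genes of branched-chain amino acid breakdown passed as a list (camera adjusted p = 3.8e-05, p = 0.215 with an estimated correlation) with 0 of 22 past the test over all genes and 2 lower adjusted over the list alone. Mccc1 and Mccc2, subunits of methylcrotonoyl-CoA carboxylase, had log2 changes of -0.75 and -0.76 (limma adjusted p = 0.0968 and 0.0948). Both passed as lower with median ratio scaling (0.0493 and 0.0482), quantile normalization (0.0446 and 0.0428), the muscle score as covariate (0.0268 and 0.0169), the exon length trend removed (0.0372 and 0.0460) and the GC trend removed (0.0311 and 0.0402). For fatty acid oxidation, Cpt2 fell by 0.87 on the log2 scale (adjusted p = 0.0212) and 26 of 27 did not pass (2 lower adjusted over the list alone; camera adjusted p = 0.0828, p = 0.55 with an estimated correlation). The list passed as lower without Flox 3 (0.0325), Flox 4 (0.0141), Ad-GHRKO 2 (0.0180) or Ad-GHRKO 4 (0.0116). The call of Cpt2 ended without any of 5 single libraries (up to 0.0696). For insulin signalling and glucose uptake, Pik3r1, a regulatory subunit of PI3 kinase, fell by 1.01 (adjusted p = 0.0224) and 28 of 29 did not pass (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.534, p = 0.689 with an estimated correlation). The call of Pik3r1 ended without any of 6 single libraries (up to 0.0650). No glycolysis gene of 19 passed over all genes or over the list alone (camera adjusted p = 0.167, p = 0.322 with an estimated correlation). The glycolysis list passed as lower without Ad-GHRKO 1 (0.00345), without Flox 1 (0.0320) and with the B cell score as covariate (0.0232). Its score was 6.63, 6.21 and 6.54 in the muscle-rich libraries Ad-GHRKO 1, Flox 3 and Flox 5, against 4.88 to 5.14 in the other Ad-GHRKO and 4.97 to 5.19 in the other Flox libraries.

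Immediate early and heat shock genes were higher as a list in Ad-GHRKO, with 6 of 23 up, none down and 17 not past the test, and 15 higher adjusted over the list alone. Fos rose from 13.6 ± 3.90 to 96.1 ± 52.4 FPKM (log2 change 2.58, SE 0.36, adjusted p = 0.00436), Egr1 from 6.86 ± 1.43 to 46.5 ± 26.0 FPKM (adjusted p = 0.00454) and Junb from 11.8 ± 5.31 to 55.1 ± 23.4 FPKM (adjusted p = 0.0140). These genes also respond to tissue handling. The list had camera adjusted p = 7.84e-12, and p = 0.0334 with an estimated correlation, where the call was lost (0.327 after adjustment). Junb overlaps Prdx2, and its call ended without the 3 muscle-rich libraries, where Junb had a log2 change of 1.69 against 2.11 with all. Genes of the unfolded protein and integrated stress response passed as a list (camera adjusted p = 0.00275, p = 0.345 with an estimated correlation) with 0 of 29 past the test over all genes or the list alone, and its call ended without the 3 muscle-rich libraries (0.122) and with array weights (0.0646). Ppp1r15a was at 7.87 ± 2.08 and 14.7 ± 4.15 FPKM (limma adjusted p = 0.0677, and 0.0392 without Ad-GHRKO 1). The circadian clock list did not pass (0 of 18 genes over all genes or the list alone; camera adjusted p = 0.764, p = 0.799 with an estimated correlation).

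Extracellular matrix genes were higher as a list, with 3 of 42 up, none down and 39 not past the test (8 higher adjusted over the list alone; camera adjusted p = 0.000114, p = 0.301 with an estimated correlation). Besides Thbs1, Ccn2 rose from 1.99 ± 0.421 to 9.48 ± 3.65 FPKM (adjusted p = 0.00252) and Tgfb3, a transforming growth factor, from 7.97 ± 1.06 to 13.0 ± 1.85 FPKM (adjusted p = 0.0285). The call of Tgfb3 ended without any of 8 single libraries (up to 0.0737). In the senescence and secretory list, 4 of 30 rose and 26 did not pass (6 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.00802, p = 0.369 with an estimated correlation). Among them were Mmp12, the chemokine Cxcl1 with a log2 change of 2.08 (adjusted p = 0.0322) and Plaur, the urokinase receptor, with 1.23 (adjusted p = 0.0469). In Ad-GHRKO 5, Mmp12, Cxcl1 and Plaur were far above the other Ad-GHRKO libraries, at 23.7, 20.5 and 10.9 FPKM. The calls of Cxcl1 and Plaur ended without any of 8 and 9 single libraries (up to 0.0796 and 0.121), and the list's call ended without the 3 muscle-rich libraries (0.207), with array weights (0.0646) and with a filter of 5 FPKM (0.158).

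Macrophage markers were higher as a list (camera adjusted p = 7.17e-05, p = 0.283 with an estimated correlation), with 3 of 25 up and 22 not past the test (5 higher adjusted over the list alone). Trem2, a lipid receptor of macrophages, rose from 0.884 ± 0.503 to 5.88 ± 2.19 FPKM (adjusted p = 0.00394), and Itgax, an integrin, had a log2 change of 1.59 (adjusted p = 0.0447, ending without any of 8 single libraries, up to 0.118). The abundant markers Lyz2 and C1qb were at 525 ± 289 and 227 ± 114 FPKM in Flox and 777 ± 395 and 273 ± 68.1 FPKM in Ad-GHRKO (adjusted p = 0.537 and 0.644). Interferon response genes were lower as a list (camera adjusted p = 0.000142, p = 0.373 with an estimated correlation, and 0.0840 after adjustment without the 4 libraries with muscle reads), and 1 of 43 fell over all genes and over the list alone. It was Ifi27l2a, from 5027 ± 1458 to 1544 ± 929 FPKM (adjusted p = 0.0311, ending without any of 7 single libraries, up to 0.0833). T and NK cell genes were lower as a list (camera adjusted p = 0.0469, p = 0.41 with an estimated correlation) with 0 of 12 past the test over all genes or the list alone, and the call ended without any of 6 single libraries (up to 0.237) and under 7 other settings (up to 0.150). Nkg7 was at 5.89 ± 3.52 and 2.89 ± 1.24 FPKM (adjusted p = 0.387).

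Lists of other cell types did not pass with all 10 libraries. Nos3, the endothelial nitric oxide synthase, fell from 10.1 ± 0.999 to 4.89 ± 1.38 FPKM (log2 change -0.94, adjusted p = 0.0132; -0.79 and 0.0618 without the 4 libraries with muscle reads), the 1 of 21 endothelial genes past the test over all genes and over the list alone (camera adjusted p = 0.768, p = 0.927 with an estimated correlation). Cspg4, a pericyte proteoglycan, fell from 6.87 ± 1.30 to 3.09 ± 0.452 FPKM (adjusted p = 0.00811), the 1 of 15 pericyte and smooth muscle genes (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.313, p = 0.593 with an estimated correlation). Acta2, smooth muscle actin, was at 56.4 ± 17.2 and 154 ± 80.5 FPKM (adjusted p = 0.0629, and 0.0203 without Ad-GHRKO 1). No gene passed over all genes or the list alone among 23 adipose progenitor, 10 B and plasma cell, 10 neutrophil and mast cell, 10 Schwann and nerve, 8 erythroid and 6 skeletal muscle genes. Their camera adjusted p were 0.17, 0.214, 0.154, 0.71, 0.0811 and 0.614, with p = 0.665, 0.53, 0.459, 0.873, 0.319 and 0.793 with an estimated correlation. Some passed with fewer libraries: erythroid genes as lower without Flox 1 (0.0369), Flox 4 (0.0267), Flox 5 (0.0368) or Ad-GHRKO 5 (0.0239), skeletal muscle as lower without Ad-GHRKO 1 (0.0425), neutrophils and mast cells as lower without Flox 2 (0.0153), adipose progenitors as higher without Flox 4 (0.00154) and Schwann and nerve genes as lower without Ad-GHRKO 5 (0.0354). Erythroid genes also passed with no filter, TPM rescaling and array weights (0.0138, 0.0275 and 0.0408), neutrophils and mast cells with no filter (0.00661) and adipose progenitors with a filter of 5 FPKM (0.0412). Acta1, skeletal muscle actin, was at 3712 ± 5235 and 4142 ± 9048 FPKM (adjusted p = 0.989). The mammary and other epithelium list had 4 genes at tested levels and was not tested as a list, and in it the estrogen receptor gene Esr1 fell by 0.76 on the log2 scale (adjusted p = 0.0163, and 0.0538 without Ad-GHRKO 3; 1 higher and 1 lower adjusted over the list alone). The keratinocyte list also had 4 genes, with 0 past the test over all genes or the list alone. The sex chromosome list had 4 genes with 0 past the test over all genes and 1 higher adjusted over the list alone. Xist was at or below 0.0239 FPKM and Ddx3y at 7.4 FPKM or more in every library.

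In antioxidant defence, 3 of 34 genes fell and 31 did not pass (4 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.845, p = 0.939 with an estimated correlation). These were Gsta4, a glutathione transferase, from 39.3 ± 8.77 to 15.1 ± 5.45 FPKM (adjusted p = 0.0151), Sod1, a superoxide dismutase, from 133 ± 25.7 to 73.1 ± 12.8 FPKM (adjusted p = 0.0311), and Gpx3, a glutathione peroxidase, from 1021 ± 309 to 411 ± 101 FPKM (adjusted p = 0.0358). The calls of Sod1 and Gpx3 ended without any of 7 and 8 single libraries (up to 0.0843 and 0.0955). In autophagy and lysosome, Atp6v0d2 was higher and Bnip3, a mitophagy receptor, lower with a log2 change of -0.83 (adjusted p = 0.0341, ending without any of 7 single libraries, up to 0.0998), and 37 of 39 did not pass (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.303, p = 0.684 with an estimated correlation). Among inflammatory cytokines and chemokines, Cxcl1 was the 1 of 27 past the test (4 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.145, p = 0.591 with an estimated correlation). That list passed as higher without Flox 1 (0.0412) or Flox 4 (0.0222) and with no filter (0.00702). No cell cycle gene of 18 passed over all genes or the list alone (camera adjusted p = 0.694, p = 0.812 with an estimated correlation). Camera compares a list with the other genes, and its direction differed in sign from the mean for antioxidant defence, circadian clock, cell cycle and endothelial genes, and from the median for insulin signalling and growth hormone signalling.

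Among the gene ontology processes annotated in the table, 81 of 1766 passed camera, with 42 higher and 39 lower. Assembly of respiratory complex I (45 genes, median log2 change -0.43, adjusted p = 1.79e-15) and translation (295 genes, median -0.23, adjusted p = 1.48e-11) were lower, as was electron transport from cytochrome c to oxygen (19 genes, median -0.63, adjusted p = 3.35e-09). With an estimated correlation their unadjusted p = 0.0209, 0.135 and 0.00281, and their calls were lost. Cell adhesion (200 genes, median 0.22, adjusted p = 0.00307), positive regulation of stress fiber assembly (43 genes, median 0.22, adjusted p = 0.00372) and integrin signalling (58 genes, median 0.23, adjusted p = 0.00901) were higher, with p = 0.388, 0.0692 and 0.296 with an estimated correlation. With an estimated correlation 0 processes passed camera after adjustment, and 17 had an unadjusted p under 0.05. The count of 81 was 44 without Flox 2, 45 without Flox 5 and 49 without Ad-GHRKO 3. Other splits of the libraries gave at least as many processes in 21 of 100 cases, the real one included.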

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

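The test of independent muscle genes, that of fasting-induced genes and the counts over other splits were set before their results were seen, and the other tests below only afterwards. Among 214 sets of 5 values examined, a single library lay far from the other 4 of its genotype in 25, where chance gives about 1 in 20, or 10.7. Ad-GHRKO 1 accounts for 8 of them and Ad-GHRKO 5 for 6.

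In Ad-GHRKO 1, reads on the skeletal muscle list were at 18.4%, Acta1 at 20326 FPKM, Cox8b at 178 FPKM and Fabp4 at 842 FPKM. Its scores were 6.63 for glycolysis, 4.97 for antioxidant defence, 1.04 for T and NK cells and 2.25 for neutrophils and mast cells. In Ad-GHRKO 5, Mmp12 was at 23.7 FPKM, Cxcl1 at 20.5, Plaur at 10.9, Ppp1r15a at 21.8 and Gm23935 at 34188 FPKM, and its depth was the lowest at 14.6 M reads. In the other Ad-GHRKO libraries, Ifi27l2a was at 3153 FPKM and Bnip3 at 42.7 FPKM in Ad-GHRKO 4, and Gpx3 at 238 FPKM in Ad-GHRKO 2. Among Flox libraries, Igf1 was at 28.8 FPKM and Cdkl4 at 1.88 FPKM in Flox 2, Thbs1 at 27.8 FPKM in Flox 1, Fos at 20.3 FPKM and Rasd1 at 117 FPKM in Flox 4, H2-Q10 at 17.8 FPKM and Aacs at 98.1 FPKM in Flox 5, and Esr1 at 4.59 FPKM in Flox 3.

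The count of 280 changed genes was reached by 2 of 100 splits of the 10 libraries into 5 and 5, the real one included. Such a count was rare among the splits, but chance is not excluded for it. The highest other split gave 381 genes and exchanged Flox 4 with Ad-GHRKO 1, placing the 3 muscle-rich libraries together. The 15 fixed lists were reached by 47 of 100 splits, with 23 as the highest other, and the 81 processes by 21 of 100, with 159 as the highest other. Chance is not excluded for the number of lists or of processes either, and splits reached these counts more often.

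Skeletal muscle transcripts were abundant in Flox 3, Flox 5 and Ad-GHRKO 1. Genotype is argued against as the whole cause, since both genotypes held libraries rich and poor in reads on the muscle list. These were 7.29% and 10.4% of reads in 2 Flox libraries and 0.007% to 0.016% in the others, and 18.4% in 1 Ad-GHRKO library and 0.012% to 0.239% in the others (exact permutation p = 0.778). Muscle tissue in the dissected sample is a candidate explanation: of 20 muscle genes outside the fixed list, 95% in each of the 3 libraries were over 10 times the median of the 6 libraries with least muscle. Acta1 reached 20326 FPKM in Ad-GHRKO 1.

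The respiratory chain list was lower in Ad-GHRKO with the preset correlation, and its call was lost with an estimated one (p = 0.0396, 0.327 after adjustment). Muscle tissue is argued against as the whole cause, because without the 3 muscle-rich libraries the list mean relative to all genes was -0.65, against -0.55 with all. Every Ad-GHRKO list score also lay below every Flox list score without them. That adds nothing, because it held with all 10 libraries and leaving some out could not undo it. Exon length, GC content and expression level are argued against as the whole cause of the list's value. Its mean was -0.52, where 10000 matched random lists averaged -0.06 and ran from -0.28 to 0.15. Those lists were drawn gene by gene, while the subunits vary together (estimated correlation 0.53). Percentile 0 among them therefore overstates how unusual the value is. Relative to all genes the list mean was -0.47 with the exon length trend removed and -0.54 with the GC trend removed. For single subunits the calls were not all kept: without the exon length trend Cox5b went from -0.79 (SE 0.14) to -0.69 (SE 0.17), Uqcrq from -0.91 (SE 0.20) to -0.83 (SE 0.23) and Atp5k from -0.84 (SE 0.18) to -0.72 (SE 0.22), smaller changes with larger errors, and without the GC trend Uqcrq was at -0.92 (SE 0.25) and Atp5k at -0.80 (SE 0.22), with larger errors, and these calls ended. A smaller share of adipocytes cannot be told apart from a change within them. The macrophage score minus the endothelial score differed by 0.66 (exact permutation p = 0.0635, interval -0.05 to 1.32). That test cannot decide the adipocyte share, because it uses no adipocyte marker and can move with macrophages alone. The genotype effect named by the design also stays open as a hypothesis.

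The de novo lipogenesis list was lower in Ad-GHRKO with the preset correlation, and its call was lost with an estimated one (p = 0.0282, 0.327 after adjustment). Muscle tissue is argued against as the whole cause, since the list mean relative to all genes was -0.87 without the 3 muscle-rich libraries and -1.11 with all. Less food taken before necropsy may have contributed and cannot be told apart: 9 genes that fasting induces in fat were 0.47 higher relative to all genes (exact permutation p = 0.0635, interval -0.04 to 1.01). A smaller share of adipocytes needs the list to be no lower than the adipocyte markers, and its score minus theirs was -0.65, which points against that share, but the difference missed the threshold (exact permutation p = 0.0873), so it cannot be told apart. The genotype effect stays open as a hypothesis.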

How the results depend on the processing

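The alternatives that leave out several libraries, use voom or remove a trend with exon length or GC content were chosen after seeing the data, and the others before; the cause of the changes below was not tested except where stated. Ghr stayed lower and past the threshold under each alternative, with log2 changes from -2.49 to -2.29 when 1 library was left out. All of the 280 genes that were tested under an alternative kept their direction. That is a weak check, because the genes were selected in the same libraries. For 255 of them the genotypes did not overlap, so leaving out libraries could not turn these. The genes changed in Ad-GHRKO (total, higher, lower) were 117, 36 and 81 with no filter, where 31285 genes were tested; 531, 237 and 294 with median ratio scaling; 565, 224 and 341 with quantile normalization; 1695, 1003 and 692 with array weights; 833, 318 and 515 with the skeletal muscle score as covariate; and 427, 195 and 232 with the epithelium score. They were 777, 378 and 399 without the 3 muscle-rich libraries, 675, 362 and 313 without the 4 libraries with muscle reads, 532, 247 and 285 with the exon length trend removed, and 563, 266 and 297 with the GC trend removed. With TPM rescaling 234 changed, 141 higher and 93 lower. A block for the replicate number gave 85, 25 and 60. The labels do not say whether the numbers pair the samples. Deviations from the group means correlated between same-numbered libraries at -0.489, 0.394, -0.0339, 0.28 and -0.259. These values cannot settle it, because the libraries also differ in muscle reads. Leaving out 1 library gave 116 to 1185 genes, 41 to 778 higher and 75 to 407 lower. The other settings gave 230 to 315 genes. The number of lists past the threshold, 15 with all libraries, was 7 without the 4 libraries with muscle reads, 4 by fry and 0 with an estimated correlation. It was 14 to 19 when 1 library was left out, where 14 or 15 of the 15 stayed past and the others were gained. Fry's mixed test passed 17. The 81 processes became 50 with array weights, 46 with the exon length trend removed, 0 with an estimated correlation, and 44 to 114 when 1 library was left out. By permutation 0 list scores passed after adjustment under each setting tried, and 6 passed an unadjusted 0.05 with all libraries. The smallest p that 5 against 5 libraries allow is 0.00794, and it is larger with fewer libraries. Adjustment over 33 lists can then be passed only when several lists reach that p, so the 0 does not show that the lists are alike. Of the 55 named genes past the threshold, 30 lost it with no filter, 31 with the block (among them Thbs1, Ccn1, Sfrp5, G0s2, Agpat2, Gsta4 and Nos3), 11 with TPM rescaling, 11 without the 3 muscle-rich libraries and 20 without the 4 libraries with muscle reads (among them Acaca, Angptl8, Agpat2, Junb and Nos3). Some named genes not past the threshold with all libraries passed elsewhere. Ppp1r15a did so with median ratio scaling, quantile normalization, TPM rescaling, array weights, each of the 3 covariates, either trend removed and without Ad-GHRKO 1. Acta2 passed in the same settings except the B cell and epithelium covariates. Retn passed with a filter of 5 FPKM, median ratio scaling, quantile normalization, array weights, the muscle covariate, either trend removed and without Ad-GHRKO 1 or 2, and Cox8b with array weights, the muscle covariate and without Ad-GHRKO 1, the 3 or the 4 libraries.

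No named gene or list past the threshold with all libraries turned direction, and some that were not past it did. Their values are log2 changes, for lists the mean minus that of all genes, and a list's direction is that of camera. For Fabp4 it was 0.230 with quantile normalization, 0.0338 with TPM rescaling, 0.0993 with array weights and -0.198 to 0.216 with 1 library left out (turned without Flox 1 and Ad-GHRKO 1), against -0.0867 with all libraries. For antioxidant defence it was 0.0560 with quantile normalization, 0.0460 with array weights, 0.0345 with the exon length trend removed and -0.0655 to 0.0266 with 1 library left out (turned without Flox 2, Flox 5, Ad-GHRKO 3 and Ad-GHRKO 5), against -0.00340 with all libraries. For Schwann cells and nerve it was 0.0125 with TPM rescaling, -0.485 with array weights, -0.606 without the 4 libraries with muscle reads, -0.130 with voom and -0.402 to 0.404 with 1 library left out (turned without Flox 1, Ad-GHRKO 1 and Ad-GHRKO 5, and without Ad-GHRKO 5 it passed as lower, adjusted p = 0.0354), against 0.0925 with all libraries. For endothelial cells it was -0.0185 with the block, 0.0367 with the B cell score, 0.0194 with the epithelium score, 0.0188 without the 3 muscle-rich libraries, 0.0816 without the 4 libraries with muscle reads, 0.0240 with the GC trend removed and -0.146 to 0.0664 with 1 library left out (turned without Flox 3, Ad-GHRKO 4 and Ad-GHRKO 5), against -0.0185 with all libraries. For Acta1 it was -0.499 with array weights, -0.587 with the B cell score, -0.385 with the epithelium score and -1.55 to 1.57 with 1 library left out (turned without Flox 1, Flox 2, Flox 4 and Ad-GHRKO 1), against 0.105 with all libraries. For circadian clock it was -0.108 with array weights, -0.116 with the B cell score, -0.0655 with the epithelium score, -0.0842 with the exon length trend removed and -0.179 to 0.0824 with 1 library left out (turned without Flox 1, Flox 2 and Ad-GHRKO 1), against -0.0390 with all libraries. For pericytes and smooth muscle it was 0.0396 with array weights, against 0.172 with all libraries. For skeletal muscle it was 0.9997 without the 3 muscle-rich libraries, 0.198 without the 4 libraries with muscle reads and -2.26 to 0.774 with 1 library left out (turned without Flox 3 and Flox 5), against -0.590 with all libraries. For insulin signalling and glucose uptake it was -0.0118 without the 4 libraries with muscle reads, against -0.0908 with all libraries.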

Other observations

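The genes in the next paragraph were chosen, and the tests of macrophage genes set, after values were seen. No other hypothesis was tested.

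Adipokine and lipogenic genes outside the rule for named genes had the following levels. Lep, which encodes leptin, was at 283 ± 96.4 FPKM in Flox and 768 ± 333 in Ad-GHRKO, and Adipoq, adiponectin, at 1840 ± 466 and 933 ± 288 (n = 5 each). Neither passed in all 10 libraries (limma adjusted p = 0.115 and 0.117), and both passed without the 3 muscle-rich libraries (adjusted p = 0.0312 and 0.0276), while without the 4 libraries with muscle reads Adipoq passed (0.0406) and Lep did not (0.0550). With all 10 libraries, Lep passed with quantile normalization (0.0470) and array weights (0.00444), and Adipoq with median ratio scaling (0.0257), array weights (0.0203), the muscle score as covariate (0.00902), the exon length trend removed (0.0482) and the GC trend removed (0.0272). Over its alternatives that leave out 1 library, the adjusted p ran from 0.0086 to 0.247 for Lep and from 0.0600 to 0.257 for Adipoq. Retn, resistin, was at 785 ± 240 and 320 ± 123 FPKM (adjusted p = 0.0550, and 0.0367 and 0.0442 without Ad-GHRKO 1 and Ad-GHRKO 2). Fasn, fatty acid synthase, fell from 794 ± 520 to 88.9 ± 49.8 FPKM (adjusted p = 0.0468), Thrsp from 547 ± 274 to 135 ± 46.0 FPKM (adjusted p = 0.0276) and Elovl6 from 10.3 ± 6.22 to 1.99 ± 0.380 FPKM (adjusted p = 0.0469). Their calls ended without the 3 muscle-rich libraries (adjusted p = 0.12, 0.0641 and 0.107; log2 changes -2.47, -1.72 and -1.13, against -2.98, -1.92 and -1.70 with all), and without any of 8, 6 and 8 single libraries (up to 0.118, 0.0738 and 0.12).

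One hypothesis is that macrophages in Ad-GHRKO fat may carry more of a lipid-associated program, beyond a rise of macrophages in general. The score of 9 lipid-associated genes, among them Trem2, Itgax, Lgals3, Gpnmb and Mmp12, was 1.62 higher relative to all genes, and that of 14 general macrophage markers 0.52 higher (exact permutation p = 0.151). The difference between them was 1.10 (exact permutation p = 0.0238). That test does not decide the matter, because 5 of the 9 genes were already past the threshold in these libraries when the set was drawn up. For the 4 that were not (Gpnmb, Cd9, Spp1 and Ctsk) the difference from general markers was 0.45 (interval -0.60 to 1.51, exact permutation p = 0.341). That value does not decide it either, because these 4 were kept for not passing, which favours a small difference. The hypothesis stays open. Lgals3 itself rose from 46.2 ± 12.9 to 220 ± 173 FPKM (adjusted p = 0.0488, ending without any of 9 single libraries, up to 0.129), and Gpnmb was at 10.4 ± 4.47 and 48.2 ± 41.8 FPKM (adjusted p = 0.118).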
